A study of Mus musculus with 6 samples.

How the data were processed

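Per the labels, HCC was induced in B6 mice with NRAS and AKT by hydrodynamic tail vein injection and tissue was taken 4 weeks later. Per the labels' protocols, marrow was flushed, spleen was mashed, and tumour was digested with collagenase IV and DNase I. Tumour immune cells were enriched on Percoll, and live CD45+ cells, or live CD45-TER119- cells from tumour without Percoll, were sorted. Libraries were made with the Chromium Next GEM 5' kit, per the labels' protocols. The 6 libraries formed 6 groups with 1 library each, and how many animals each held is not given. Reads were aligned and counted with Cell Ranger 6.0.0, per the submitters' processing notes, while the headers of the 4 tumour matrices name a patch release one step later. The deposited values are raw UMI counts for 32285 genes in called cells, per the file headers, and were checked to be whole numbers. Everything after the counts was computed here.

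Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0 and igraph 0.11.9. Barcodes were kept with at least 200 genes and at most 15% mitochondrial UMIs in CD45+ or 30% in CD45- libraries. Scrublet scores were computed per library with an assumed rate of 0.8% for every 1000 barcodes. Scrublet called 570 doublets in marrow, 395 in spleen, 1676 in isotype tumour and 1007 in anti-Ly6G tumour CD45+ cells, which were removed, and 0 in both CD45- libraries, where no cells were removed. The CD45+ and CD45- libraries were clustered separately: counts scaled to 10000 per cell and logged, 2000 variable genes, 30 principal components, 15 neighbours, graph edges below 0.5% of the largest weight set to 0 (which the layout tool umap-learn did in the first run and all alternatives then kept), and Leiden clustering at resolution 1.0 with seed 1, which gave 31 and 21 clusters. T-cell-like cells were clustered again, with all edges, into 18 subclusters. Clusters of both fractions were named together. A cluster took the class whose markers, from lists fixed before the data were examined, had the highest mean standardised level. At least 3 of them had to be detected in 10% of its cells. No other class could hold more of its 10 leading genes. A close-scoring other lineage was allowed only with at least 3 own markers among these genes, at least 2 times those of other lineages. Otherwise it stayed unnamed. A cluster with few UMIs and none of its own markers leading stayed unnamed too. T cell subclusters were named without the rule on close-scoring lineages. The thresholds for naming, and the rule for clusters with markers of more than 1 class, were set after the clusters had been seen, and that rule was changed once, which gave CD45+ cluster 20 to the monocyte/macrophage class and cluster 28 to B cells. Classes are called by the cell type they resemble. Clusters were formed from genes that include the markers, so shares were also computed with the neutrophil or the γδ T cell markers left out of clustering.

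Shares are percent of kept cells, with exact Clopper-Pearson 95% intervals. Ratios between libraries are of UMIs summed over the cells of a class, as CPM (counts scaled to the class's UMI total), with exact conditional binomial intervals. With 1 library per group no test of a difference between groups was possible and no p-value is given; intervals treat UMIs as independent and leave out variation between cells, animals and preparations. Where a group had 0 UMIs, a floor of 3 counts was used and the ratio given as a bound. Classes were compared with at least 50 cells on both sides. Comparisons covered neutrophils in tumour against marrow and spleen, and each class in anti-Ly6G against isotype tumour.

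Named genes were, by a rule fixed before the data were examined, up to 10 higher and 10 lower per comparison, ranked by the interval bound nearest to 0, among genes with at least 50 CPM in either group, at least 100 UMIs in both together and a log2 ratio of at least 1 in size. Receptor segment, mitochondrial, ribosomal, haemoglobin, Xist, Y-linked and unnamed gene models were left out, as were genes prone to free RNA, whose CPM in another class of the same library was at least 10 times that in the class, in both libraries. The CD45+ libraries held no hepatocyte class and the CD45- libraries no named immune class. This rule therefore could not screen hepatocyte or tumour RNA in immune cells, or immune RNA in CD45- cells. Ly6g, Cd274, Siglecf, Arg1, Ifng, Gzmb, Pdcd1, Foxp3, H2-K1, B2m, Afp and Alb were named in any case, in the classes they bear on. The 28 gene lists were fixed before the data were examined. For each list the median log2 ratio of its members with at least 10 UMIs was set beside 10000 random lists matched on expression in 20 bins, its interval came from 500 resamples of the counts, and members were counted as higher or lower where the ratio passed 1.5-fold and the interval excluded 1. The main lists fixed in advance were the tumour-associated neutrophil, cytotoxicity, interferon-γ, MHC class I and hepatocyte function lists in the classes they belong to. The other lists, and the example genes of each list, were chosen for the text after their values were seen.

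The ratio step was tested on simulated counts drawn from the real means, with 200 changed genes, 100 of them by 2-fold and 100 by 4-fold. The changed genes were taken from well-counted genes only, so recovery of changes in genes with few UMIs was not measured. Simulated counts were independent, as the intervals assume, so the simulation checks the computation and not the variation between cells or animals. For neutrophils in anti-Ly6G against isotype tumour (11603 genes), 100% of both sizes were recovered in direction, and for hepatocyte/HCC-like cells (14391 genes) 100% too. The intervals held the true ratio in 78% of the 2-fold and 84% of the 4-fold genes for neutrophils, and in 83% and 84% for hepatocyte/HCC-like cells, because the changed genes moved the library totals; with that shift taken off they held it in 94%, 92%, 92% and 92%. Among unchanged genes, 1.53% (neutrophils) and 0.847% (hepatocyte/HCC-like cells) passed 1.5-fold with an interval that excluded 1. A list shift of 0.5 was recovered as 0.47 and 0.49.

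Alternatives fixed in advance were stricter mitochondrial limits of 7.5% and 15%, at least 500 genes per cell, list members with at least 50 UMIs or without those prone to free RNA, doublets kept, Leiden resolutions of 0.5 and 2.0, per-cell class scores in place of clusters, means of per-cell CPM, median-of-ratios scaling, cells thinned to 1000 or 2000 UMIs, and shares among cells other than neutrophils. Those added after seeing the data were neutrophils by cluster or with the isotype cluster mix, single clusters left out, marker genes left out of clustering, clustering with the weak edges, T cell subclustering at other resolutions, and, for CD45- cells, a mitochondrial minimum of 0.5% or a doublet score limit of 0.3. Trajectories, velocity, receptor sequences and copy number were not analysed here.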

Results

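Immune cells and tumour cells were profiled from mice carrying hepatocellular carcinoma (HCC) driven by NRAS and AKT, 2 oncogenes delivered to the liver by hydrodynamic tail vein injection. Mice were killed 4 weeks after tumour induction. The 6 single-cell 5' libraries were 1 each of CD45+ (immune) cells from bone marrow, spleen, tumour of isotype-treated mice and tumour of anti-Ly6G-treated mice, and of CD45-TER119- cells from tumours under the same treatments. Anti-Ly6G is an antibody against a surface protein of mouse neutrophils, given to deplete them. There were no replicates, so differences are stated for these libraries only, and all ranges are 95% intervals that cover counting error alone, exact for shares and gene ratios and from resampled counts for list medians. The libraries held 96585551 UMIs in 11425 barcodes (bone marrow), 58495618 in 10805 (spleen), 84307588 in 15731 (tumour CD45+ isotype), 84065131 in 13582 (tumour CD45+ anti-Ly6G), 96678981 in 13360 (tumour CD45- isotype) and 87780524 in 10626 (tumour CD45- anti-Ly6G). After filtering, 10801, 10356, 13934, 12473, 13089 and 10418 cells were kept, in the same order. The bone marrow library held 29389 UMIs of the X-inactivation transcript Xist and none of the Y-linked genes, while the other 5 libraries carried Y-linked transcripts, so tissue and sex cannot be separated in comparisons with marrow.

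The first comparison addressed whether anti-Ly6G lowered the neutrophil share of tumour immune cells. Neutrophil-like cells, short-lived phagocytes, made up 31.9% of the isotype tumour library (31.2 to 32.7, Clopper-Pearson, 4449 cells) and 17.4% of the anti-Ly6G library (16.8 to 18.1, 2172 cells), a fold of 0.545 (0.518 to 0.574). Ly6g, which encodes the antibody's target, was higher in the neutrophils of the anti-Ly6G library (662 CPM) than in those of the isotype library (111 CPM), a log2 ratio of 2.58 (2.49 to 2.67). The remaining neutrophil-like cells also fell in other clusters: in the isotype library most lay in cluster 13 (2620 cells) and cluster 14 (1600), and in the anti-Ly6G library in cluster 11 (1243) and cluster 13 (729), with 54 cells in the immature cluster 2 against 8. Ly6g was also higher within cluster 11 (log2 0.66, 0.50 to 0.82) and within cluster 13 (log2 2.5, 2.01 to 3.0), while the interval for cluster 14 included 0 (log2 0.27, -0.09 to 0.61). Monocyte/macrophage-like cells made up 16.2% of the anti-Ly6G library and 12.2% of the isotype library (fold 1.33, 1.25 to 1.42), and plasmacytoid dendritic cells, the main interferon-producing dendritic cells, 1.37% and 0.861% (fold 1.59, 1.25 to 2.03). B cells (35.6% and 29.9%), T cells (22.4% and 20.2%) and NK/ILC1 cells (3.66% and 3.09%) were also larger shares of the anti-Ly6G library. Counted among cells other than neutrophils, the B cell (fold 0.981, 0.940 to 1.02), T cell (fold 0.916, 0.869 to 0.965) and NK/ILC1 (fold 0.976, 0.854 to 1.12) ratios turned to below 1, the monocyte/macrophage ratio was 1.10 (1.03 to 1.17) and the plasmacytoid dendritic cell ratio 1.31 (1.03 to 1.67). Cluster 20, which carried neutrophil RNA, supplied 197 of the 2024 monocyte/macrophage-like cells under anti-Ly6G and 54 of the 1697 under isotype. The class's other clusters, 15 and 17, held 140 and 1687 cells under anti-Ly6G, where 10301 cells were not neutrophil-like. Under isotype they held 123 and 1520 of 9485 such cells. The ratio without cluster 20 was not computed, but these counts place most of the excess among cells other than neutrophils in that cluster. Conventional dendritic cells made up 1.51% and 1.31% (fold 1.15, 0.931 to 1.41, and 0.946, 0.768 to 1.17, among cells other than neutrophils). Few cells were granulocyte-monocyte precursors (40 under anti-Ly6G and 3 under isotype, fold 14.9, 4.74 to 75.3) or plasma cells (24 and 11, fold 2.44, 1.15 to 5.51). Clusters without a class name held 1.29% of the anti-Ly6G and 0.445% of the isotype library. The shares are those of cells that passed Percoll enrichment, the CD45+ sort and filtering, and neutrophil-like cells had a median of 4572 UMIs in the anti-Ly6G library and 2340 in the isotype library.

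**Figure D1:**
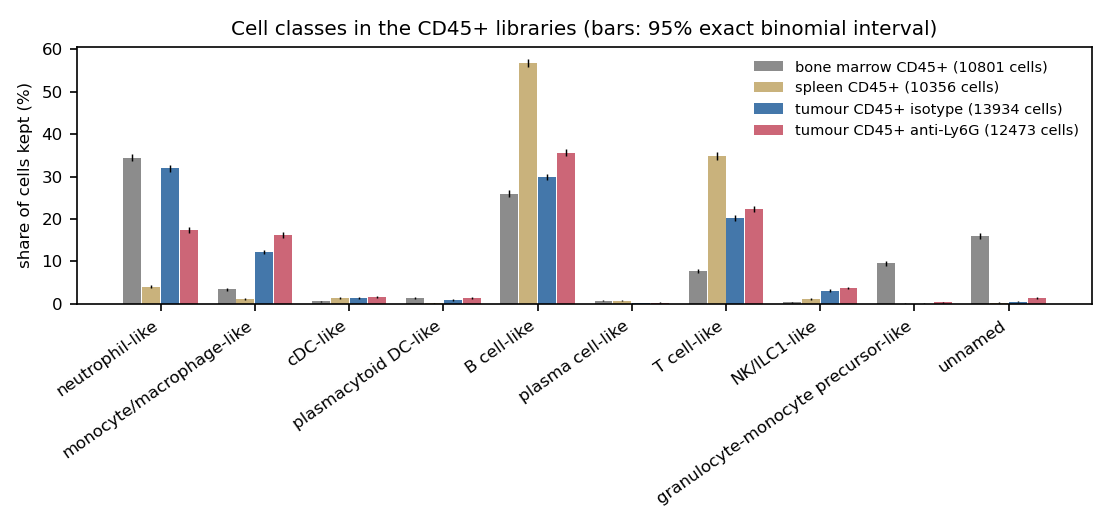
Percent of the kept cells (y axis) in each cell class (x axis) for the 4 CD45+ libraries, with exact 95% intervals from counting error as error bars. Neutrophil-like cells made up 31.9% of the isotype tumour library and 17.4% of the anti-Ly6G tumour library.

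The immune cells of the isotype tumour were set beside those of marrow and spleen to show which cells were frequent in the tumour. Neutrophil-like cells made up 4.02% of spleen (3.65 to 4.41), so that their share was 7.95-fold higher in tumour (7.19 to 8.81), and 34.5% of marrow (33.6 to 35.4), close to the share in tumour (fold 0.926). T cells made up 34.8% of spleen, 20.2% of tumour and 7.72% of marrow. B cells made up 56.7%, 29.9% and 26.0%, and NK/ILC1 cells 1.04%, 3.09% and 0.361%. Monocyte/macrophage-like cells were 12.2% of tumour, 1.14% of spleen and 3.35% of marrow. Their log2 ratio of tumour to marrow was 1.86, but other ways of filtering or assigning cells gave 0.084 (doublets kept) to 2.64 (at least 500 genes per cell), so that its size was not settled. Clusters without a class name held 16.1% of marrow (cluster 1, with precursor and monocyte markers, 1331 cells, and cluster 12, with basophil or mast cell and progenitor markers, 404 cells), 0.241% of spleen and 0.445% of the isotype tumour.

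Neutrophils of the tumour were compared with those of the marrow, where neutrophils are made, to describe the cells that had entered the tumour. Genes of the tumour-associated neutrophil list were higher in tumour and granule protein genes lower. Ltc4s, the synthase of leukotriene C4, stood at 221 CPM in tumour and 0.601 CPM in marrow (log2 8.52, 7.64 to 9.59). Il1a, an inflammatory cytokine, had a log2 ratio of 7.73 (6.61 to 9.18), and Ccrl2, a chemerin-binding receptor, of 6.54 (6.40 to 6.69). The cell-cycle inhibitor Cdkn1a (log2 6.01, 5.80 to 6.21), the regulator of G-protein signalling Rgs1 (log2 6.96, 6.58 to 7.38) and the adaptor Scimp (log2 7.52) were higher too. Hic1, Hspa1a, Gpc3 and Cxcl3 completed the 10 genes ranked highest (log2 9.03, 8.88, 8.56 and 6.40). Hspa1a encodes a heat-shock protein, and Cxcl3 also served to name clusters. Gpc3 is an HCC marker, and the free RNA rule could not screen tumour-cell RNA in these cells. Among the 10 lowest, Cybb, the catalytic subunit of the phagocyte oxidase, had a log2 ratio of -4.90, the glutathione S-transferase Mgst2 of -4.87, the acute-phase protein Orm1 of -5.27 and the protease inhibitor Serpinb1a of -4.23. The other 6 were Camp, Ltf, Ngp, Elane, Mpo and Itgb2l, which also served to name clusters. Ly6g was lower in tumour (log2 -2.54, -2.62 to -2.45). Cd274, which encodes the checkpoint ligand PD-L1, stood at 34.5 CPM in tumour and 2.52 CPM in marrow (log2 3.77, 3.31 to 4.27), and Siglecf, a lectin reported on tumour neutrophils, at 145 and 3.66 CPM (log2 5.31, 4.94 to 5.70).

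Among the gene lists, all 35 measured members of the tumour-associated neutrophil list were higher by at least 1.5-fold in tumour, with a median log2 ratio of 3.37 (3.23 to 3.5) at the 100th percentile of 10000 random lists of like expression. Examples were Il1a, Ccrl2, Cxcl3 (log2 6.40) and the neutrophil chemoattractant Cxcl1 (log2 6.15). All 19 measured granule protein genes were lower, with a median of -4.62 (-4.88 to -4.35), as in the antimicrobial peptide Camp (log2 -7.52), lactoferrin Ltf (log2 -6.92), neutrophil elastase Elane (log2 -6.48) and myeloperoxidase Mpo (log2 -6.02). Of 23 suppressive myeloid genes, 17 were higher and 3 lower, with a median of 2.30 (2.27 to 2.33). Higher members included Pdcd1lg2, a PD-1 ligand (log2 5.09), the prostaglandin synthase Ptgs2 (log2 4.77) and Il1b (log2 4.73), and the lower ones were Ptges (log2 -3.47), S100a8 (log2 -1.94) and S100a9 (log2 -1.45). Of 27 hypoxia and glycolysis genes, 18 were higher and 1 lower (median 1.52, 1.38 to 1.61), with Hilpda, a hypoxia-induced lipid droplet protein, at log2 4.59 and the collagen hydroxylase P4ha1 at log2 4.34. All 22 dissociation and immediate early genes were higher (median 3.23, 3.20 to 3.26), and only the tumour was digested with collagenase. The median over all measured genes was 0.50. RNA of other cell types was higher in the tumour neutrophils too: 16 of 18 hepatocyte function genes (10 of the 18 had 0 UMIs on one side, and the median was 4.22 against the floor of 3 counts), 21 of 22 cytotoxicity genes (median 2.86 against that floor, 17 prone to free RNA) and 14 of 16 MHC class II genes (median 2.56, 13 prone). Marrow neutrophils lay mostly in the immature cluster 2 (2391 of 3724 cells). Without that cluster these differences were smaller: the tumour-associated neutrophil median was 2.20, the granule median -2.69, the suppressive myeloid median 1.10, and the log2 ratios of Il1a, Ccrl2 and Orm1 were 5.51, 4.50 and -0.18.

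Against spleen, a peripheral site, the contrast was smaller and the granule genes did not lead. The neutrophil chemoattractant Cxcl3 had a log2 ratio of tumour to spleen of 5.63 (4.59 to 6.95), Ccrl2 of 4.56, and the itaconate-producing enzyme Acod1 of 4.53. The orphan nuclear receptor Nr4a3 had 938 UMIs in tumour and 0 in spleen, which makes it at least 22.6-fold higher against a floor of 3 counts, and Il1a had 880 and 0, at least 21.2-fold higher. Hilpda (log2 4.67), the chemokine Ccl4 (log2 4.08), the NF-κB inhibitor Tnfaip3 (log2 4.03), Cdkn1a (log2 3.97) and G0s2, an inhibitor of lipolysis (log2 3.49), completed the 10 highest, of which Cxcl3, Acod1 and G0s2 also served to name clusters. The 10 lowest included interferon-induced Oasl2 (log2 -2.22) and Rtp4 (log2 -2.19), the protease Ctse (log2 -2.65), Ctla2a (log2 -3.34), the immunoglobulin joining chain Jchain (log2 -2.61) and the histone gene Hist1h2ap (log2 -2.5). Of 35 tumour-associated neutrophil genes, 32 were higher in tumour (median 2.60, 2.38 to 2.90, 100th percentile). Of 29 measured type I interferon response genes, 24 were lower (median -1.22, -1.43 to -1.08), with Usp18 at log2 -2.72, Ifit3b at -2.43 and Cmpk2 at -2.30. RNA of other cell types differed as well: 7 of 16 naive and memory T cell genes (median -0.98) and 5 of 16 MHC class II genes (median -0.76) were lower, and 5 of 18 hepatocyte function genes higher. Of 18 mature circulating neutrophil genes, 8 were lower and 1, the decoy receptor Il1r2 (log2 1.73), higher (median -0.54, -0.60 to -0.46). Of 26 hypoxia and glycolysis genes, 13 were higher and none lower (median 0.67, 0.54 to 0.91), among them the angiogenic factor Vegfa (log2 2.45). Dissociation and immediate early genes had a median of 0.87 (0.78 to 0.98). Ly6g was at 111 CPM in tumour and 168 CPM in spleen (log2 -0.60, -0.86 to -0.34), Cd274 was higher in tumour (log2 1.37, 0.52 to 2.39), and so was Siglecf (log2 3.0, 2.27 to 3.84). H2-K1 had a log2 ratio of 0.23, which turned to -0.26 with doublets kept. The spleen library held 416 neutrophil-like cells, 333 of them in cluster 14.

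Neutrophils left in the anti-Ly6G tumour were then compared with those of the isotype tumour. Most granule protein genes were higher in them, and most tumour-associated neutrophil genes lower. Cd177, a neutrophil surface glycoprotein, stood at 687 CPM under anti-Ly6G and 80.7 CPM under isotype (log2 3.09, 2.99 to 3.19), the chemotactic protein Prok2 at 119 and 9.33 CPM (log2 3.67, 3.38 to 3.97), and the TGF-β family receptor Acvrl1 at 96.2 and 5.67 CPM (log2 4.09, 3.72 to 4.47). The interferon-induced membrane protein Ifitm6 (log2 3.12), the stefin Stfa3 (log2 3.57) and Ggt1, a glutathione-degrading enzyme (log2 3.41), were higher as well, with Ltf (log2 3.95), Camp (log2 3.5), Ngp (log2 3.46) and Itgb2l (log2 3.32), which are cluster-naming genes. Lower were the phosphatase Ptpn22 (log2 -3.04), Rgs1 (log2 -2.64), the matrix glycoprotein Thbs1 (log2 -2.58, -2.70 to -2.47), metallothionein Mt1 (log2 -2.62), Nr4a3 (log2 -2.51), the integrin Itgax (log2 -2.41), Id2 (log2 -2.32), the kinase Pim3 (log2 -2.30), the clock gene Per1 (log2 -2.26) and Bcl2l15 (log2 -5.57). Cd274 was at 9.41 CPM under anti-Ly6G and 34.5 CPM under isotype (log2 -1.87, -2.19 to -1.56), and Siglecf at 68.1 and 145 CPM (log2 -1.09, -1.21 to -0.97). H2-K1, a classical MHC class I gene, had a log2 ratio of -0.84 and B2m, its light chain, of -0.80.

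**Figure D2:**
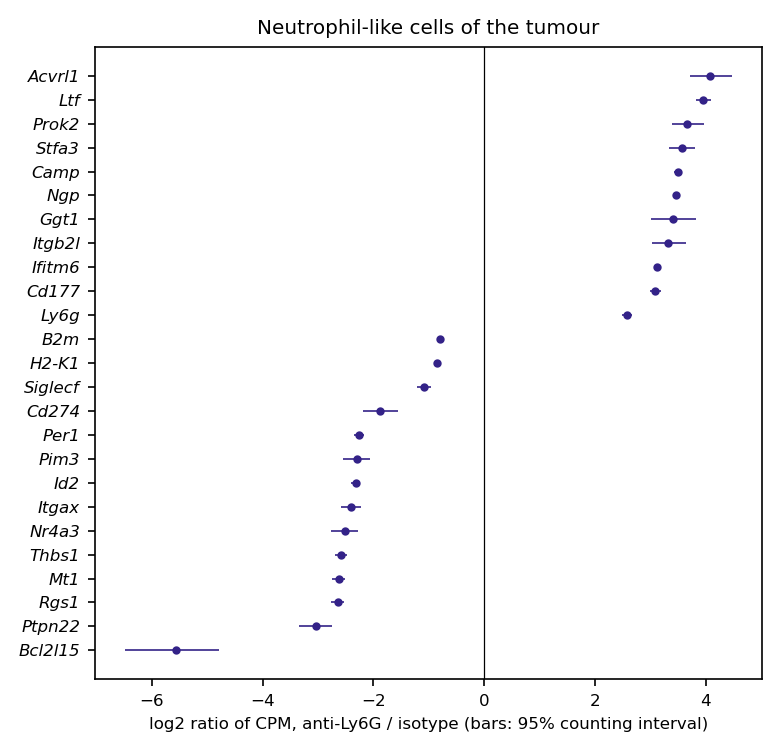
Log2 ratio of CPM, anti-Ly6G to isotype (x axis), for the named genes and Ly6g, Cd274, Siglecf, H2-K1 and B2m in neutrophil-like cells of the tumour, 1 point per gene with its 95% counting interval as a bar. Acvrl1 lies highest at 4.09 and Bcl2l15 lowest at -5.57, with Ly6g at 2.58 and Cd274 at -1.87.

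By list, 26 of 35 tumour-associated neutrophil genes were lower under anti-Ly6G and 1, the matrix protein gene Spp1 (log2 0.59), was higher (median -1.02, -1.07 to -0.96). Cxcl1 (log2 -2.00), the stress gene Gadd45b (log2 -1.88) and Ccrl2 (log2 -1.81) were among the lower ones. Of 18 granule protein genes, 14 were higher and none lower (median 1.85, 1.82 to 1.87), for example ficolin Fcnb (log2 3.57). Of 18 mature circulating neutrophil genes, 9 were higher and 2 lower (median 0.62, 0.58 to 0.67); the formyl peptide receptor Fpr1 was higher (log2 1.49), and Il1r2 (log2 -1.28) and the G-CSF receptor Csf3r (log2 -1.0) were lower. Of 22 dissociation and immediate early genes, 12 were lower (median -0.68, -0.78 to -0.62), with Fosb at log2 -2.12 and Atf3 at -1.44. The median over all measured genes was -0.56. The list differences followed the cluster mix, although the clusters were formed from genes that overlap with the lists: with the clusters weighted as in the isotype library the tumour-associated neutrophil median was 0.03, within cluster 11 it was 0.22, within cluster 13 -0.04 and within cluster 14 -0.12. The granule median was -0.33 within cluster 13 and -0.05 within cluster 14, and Siglecf turned to 0.19 with the isotype cluster mix and was -0.32 with cells thinned to 1000 UMIs.

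T cells and NK cells were compared between the treatments to ask whether lymphocytes in the tumour differed where neutrophils were depleted. Among the T cell genes named by the rule, which leaves out genes prone to free RNA, Il17a, the cytokine of type 17 cells, had the largest ratio, at 365 CPM under anti-Ly6G and 63.6 CPM under isotype (log2 2.52, 2.43 to 2.61), which is also a γδ naming gene. γδ T cells, a type 17 cytokine source that recognises antigen without classical MHC, were a larger share: 12.5% of T cells (350 cells) under anti-Ly6G and 5.45% (153 cells) under isotype, a fold of 2.30 (1.90 to 2.80). Clustering without the γδ marker genes gave a log2 ratio of 1.22 for this share. Within the γδ cluster of all CD45+ cells (cluster 21, 455 and 209 cells) Il17a stood at 2340 CPM under anti-Ly6G and 949 CPM under isotype (log2 1.30, 1.21 to 1.39). That cluster was larger than the γδ subset above. Its leading genes held 2 γδ markers and 2 of innate lymphoid cells (ILC2/ILC3), so it may include other cells. T cells outside cluster 21 held 364 Il17a UMIs in 15 of 2339 cells and 7 UMIs in 3 of 2601 cells (log2 6.02, 4.96 to 7.34). Of the 364, 254 lay in 3 cells and 356 in cluster 10, which has regulatory T cell markers. Cluster 10 held 407 cells under anti-Ly6G, while the subclustering named 143 regulatory T cells in that library. Which subset the Il17a cells of cluster 10 belong to was therefore not settled. Naive T cells made up 38.5% and 47.2% (fold 0.816, 0.752 to 0.885). This subset included subcluster 2 (417 and 557 cells), with Cd8b1 among its leading genes. It also included subcluster 6 (131 and 118 cells, median 1770 UMIs), which scored 0.89 for naive and 0.86 for CD4 T cells. The naive subset is thus not apart from CD4 and CD8 T cells. The intervals for CD8 T cells (10.5% and 10.7%), conventional CD4 T cells (5.98% and 5.94%) and regulatory T cells (5.12% and 5.27%) included no difference. The named CD8 subset held only part of the CD8 T cells, and included subclusters led by interferon and cell-cycle genes. Subcluster 7, closest to CD8 T cells but left unnamed, held 338 cells under anti-Ly6G and 411 under isotype. In the clustering of all CD45+ cells, cluster 7, also closest to CD8 T cells, held 762 and 726. T cells without a subset name made up 27.3% and 25.4%. They included subcluster 3, with B cell genes such as Cd79a and Ebf1 among its leading genes, with 317 and 212 cells. All these shares are of T-cell-like cells, so a larger share of γδ T cells or of subcluster 3 lowers the naive share by construction. The chemokine receptor Cxcr6 (log2 1.41, 1.32 to 1.5), Serpinb1a (log2 1.24), creatine kinase Ckb (log2 1.14) and the water channel Aqp3 (log2 1.04) were higher in T cells under anti-Ly6G. So were the γδ naming genes Cd163l1 (log2 1.79), Blk (log2 1.27), Tmem176a (log2 1.10) and Tmem176b (log2 1.04). Cxcr6 and Aqp3 are also among the leading genes of the γδ cluster, and Serpinb1a and Aqp3 among those of the γδ subcluster. Without the γδ cluster, Aqp3 had a log2 ratio of -0.07 and Cd163l1 of -1.05. Ifng, the effector cytokine interferon-γ, stood at 87.7 CPM under anti-Ly6G and 59.9 CPM under isotype (log2 0.55, 0.44 to 0.67), and the cytotoxic protease Gzmb at 204 and 166 CPM (log2 0.30, 0.23 to 0.37). Foxp3, which specifies regulatory T cells, had a log2 ratio of 0.25 (0.08 to 0.42) and the inhibitory receptor Pdcd1 of 0.09 (-0.04 to 0.23).

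Of 25 measured cytotoxicity genes, 5 were higher and 1 lower in T cells (median 0.30, 0.25 to 0.34, 100th percentile), with Tnf at log2 0.69 and the transcription factor Tbx21 at 0.63; 9 of the 25 are prone to free RNA from other cells. RNA of other cell types was higher in these T cells too, with medians of 0.67 for granule protein genes (5 of 13 higher), 0.72 for mature circulating neutrophil genes (7 of 17) and 0.52 for MHC class II genes (7 of 16). Without the members prone to free RNA the cytotoxicity median was 0.29. Of 23 exhaustion genes, 3 were higher and none lower (median 0.16, 0.07 to 0.24): Havcr2 (log2 1.03), Lag3 (log2 0.75, but 0.12 with cells thinned to 1000 UMIs) and Nrp1 (log2 0.67). None of 17 naive and memory T cell genes passed 1.5-fold in either direction (median -0.12, -0.17 to -0.06), such as Ccr7 (log2 -0.04) and Il7r (log2 -0.26). In NK/ILC1 cells (457 and 431 cells) the mitotic gene Ube2c stood at 89.2 CPM under anti-Ly6G and 37.1 CPM under isotype (log2 1.27, 0.91 to 1.63), and 11 of 29 proliferation genes were higher and none lower (median 0.35, 0.22 to 0.52), including Cenpf (log2 1.58) and cyclin Ccnb1 (log2 1.55). The serpin Serpina3f (log2 -1.21) and Tmem106b (log2 -1.08) were lower. Gzmb was lower in NK/ILC1 cells (log2 -0.29, -0.36 to -0.22), and Ifng had a log2 ratio of 0.20 (0.06 to 0.35), which turned to -0.03 with cells thinned to 1000 UMIs. Of 25 cytotoxicity genes in NK/ILC1 cells, 1, Tnf (log2 0.66), was higher and none lower (median 0.09, 0.05 to 0.16, 95.7th percentile), and thinning turned that median to -0.02.

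**Figure D3:**
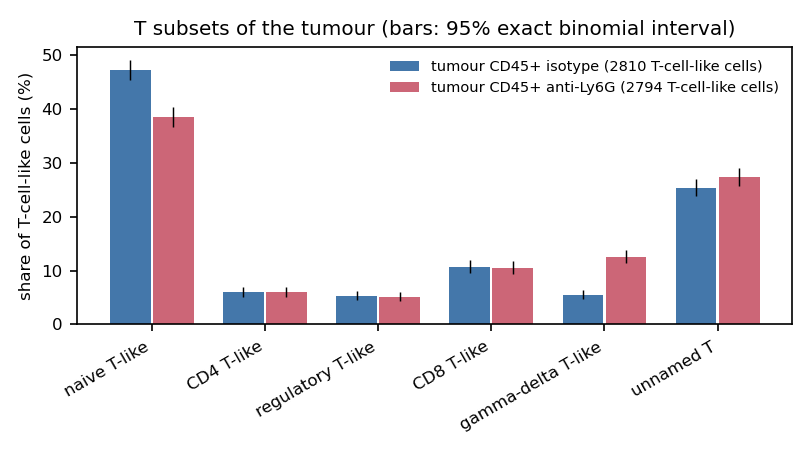
Percent of T-cell-like cells (y axis) in each T cell subset (x axis) of the isotype and anti-Ly6G tumour CD45+ libraries, with exact 95% counting intervals as error bars. γδ T cells made up 5.45% and 12.5%, and naive T cells 47.2% and 38.5%.

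Monocyte/macrophage-like cells of the tumour were compared to ask how other myeloid cells differed between the treatments. Klf9, Fkbp5, Cxcl1, Arg1 and Jdp2 were lower under anti-Ly6G, and the medians of the interferon response lists lay slightly above 0, with most members within 1.5-fold. The glucocorticoid-induced factor Klf9 stood at 45.4 CPM under anti-Ly6G and 131 CPM under isotype (log2 -1.53, -1.64 to -1.42), and Fkbp5, a co-chaperone of the glucocorticoid receptor, at 67.4 and 153 CPM (log2 -1.18). The neutrophil chemoattractant Cxcl1 stood at 22.9 and 63.4 CPM (log2 -1.47, -1.62 to -1.31), the arginine-degrading enzyme Arg1 at 25.4 and 57.7 CPM (log2 -1.18, -1.34 to -1.03), and the AP-1 repressor Jdp2 had a log2 ratio of -1.11. The 3 named genes that were higher, Camp (log2 8.40), Ltf (log2 6.17) and Lcn2 (log2 1.22), are neutrophil genes, and 10 of 19 granule protein genes were higher (median 0.86, 0.60 to 0.99). That RNA sat in cluster 20, a C1q macrophage cluster with 197 cells under anti-Ly6G and 54 under isotype, and without it the granule median was 0.22 and Lcn2 had a log2 ratio of -0.13. Hepatocyte and T cell RNA was higher in these cells too: Afp had 185 and 4 UMIs (log2 5.27), Alb 642 and 86 (log2 2.64), and 9 of 21 hepatocyte function genes (median 1.03) and 13 of 24 cytotoxicity genes (median 0.70, 18 prone to free RNA) were higher. Of 29 interferon-γ response genes, 6 were higher and none lower (median 0.27, 0.19 to 0.34, 100th percentile, 6 of the 29 prone to free RNA), including the chemokine Cxcl9 (log2 2.72, at 3.32 and 0.503 CPM) and the guanylate-binding protein Gbp2 (log2 1.01). Of 31 type I interferon response genes, 4 were higher and none lower (median 0.19, 0.13 to 0.25), among them Ifit3b (log2 0.84). The 23 MHC class I presentation genes all stayed within 1.5-fold (median 0.16, 0.10 to 0.17), with H2-K1 at log2 0.23. Of 28 hypoxia and glycolysis genes, 2 were lower and none higher (median -0.14, -0.19 to -0.11): Ankrd37 (log2 -0.73) and Hilpda (log2 -0.67). Cd274 had a log2 ratio of -0.38 (-0.67 to -0.09).

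In the CD45- libraries the question was whether tumour cells differed where neutrophils were depleted. Hepatocyte/HCC-like cells made up 79.6% of the anti-Ly6G library (8293 cells) and 81.1% of the isotype library (10612 cells, fold 0.982, 0.954 to 1.01). Cholangiocyte-like cells made up 11% and 11.5% (fold 0.955, 0.883 to 1.03), so that neither share differed detectably. The cholangiocyte-like cells held Alb at 24822 and 20944 CPM, against 29599 and 27083 CPM in hepatocyte/HCC-like cells. Their class name therefore does not set them apart from tumour cells. Clusters without a class name held 8.46% and 6.17%. In hepatocyte/HCC-like cells the gluconeogenic enzyme Pck1 stood at 589 CPM under anti-Ly6G and 1222 CPM under isotype (log2 -1.05, -1.07 to -1.03), the kinase Pim3 at 25.7 and 57.6 CPM (log2 -1.16), and Cyp2e1, a pericentral cytochrome that also names the class, at 30.2 and 104 CPM (log2 -1.79, -1.87 to -1.71). Cluster 10 of the CD45- cells, with Cyp2e1 and Pck1 among its leading genes, held 71 cells under anti-Ly6G and 300 under isotype, and without it the log2 ratio of Pck1 was -1.0 and that of Cyp2e1 -1.26. The histone gene Hist1h2ap stood at 50.7 and 19.1 CPM (log2 1.41, 1.30 to 1.51). Afp, the fetal serum protein used as an HCC marker, stood at 4935 and 3641 CPM (log2 0.44, 0.43 to 0.45), while albumin Alb (log2 0.13) and H2-K1 (log2 -0.08, -0.10 to -0.05) differed less. B2m (log2 0.04), H2-D1 (log2 -0.04), Arg1 (log2 -0.04) and the histone gene H2afz (log2 0.04) were near 0, and each turned in sign under some alternatives. Of 31 hepatocyte function genes, 1, Pck1, was lower and none higher (median 0.01, -0.00 to 0.02), and none of 23 MHC class I genes passed 1.5-fold (median -0.05, -0.09 to 0.01, 53.8th percentile). Of 25 type I interferon response genes, 11 were lower and none higher (median -0.61, -0.80 to -0.48, 7 of the 25 prone to free RNA), with Ifit3b at 0.324 and 3.17 CPM (log2 -3.29) and Ifit1 at log2 -2.24. Of 26 interferon-γ response genes, 4 were lower and none higher (median -0.19, -0.25 to -0.13), among them the chemokine Cxcl10, at 1.43 and 5.73 CPM (log2 -2.00). Of 30 cytochrome P450 and bile acid genes, 9 were lower and none higher (median -0.32, -0.40 to -0.16), including Cyp2c54 (log2 -1.07, but 0.0084 with cells thinned to 2000 UMIs), Cyp2c50 (log2 -0.97) and Cyp3a11 (log2 -0.79). Of 27 oncofetal and progenitor genes, 6 were higher and none lower (median 0.22, 0.16 to 0.28), including the fetal growth factor Igf2 (log2 2.00) the imprinted gene Peg3 (log2 0.82) and the trefoil factor Tff3 (log2 0.69, but -0.081 thinned). None of 29 proliferation genes passed 1.5-fold (median 0.16, 0.10 to 0.19), and this median turned to -0.26 in barcodes with at least 0.5% mitochondrial UMIs, where Igf2 was at log2 0.37 and Cxcl10 at -0.16. Such barcodes were the minority: 73.6% of the anti-Ly6G and 75.7% of the isotype CD45- barcodes held less than 0.5%. No mitochondrial UMI at all was seen in 47.0% and 48.4%. The nuclear transcript Malat1 stood at 309 and 328 CPM in the barcodes below 0.5%, against 6482 and 6150 CPM in the others. Neutrophil RNA was higher in the hepatocyte/HCC-like cells of the anti-Ly6G library, with S100a9 at 11.7 CPM against 0.158 CPM.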

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

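The tests behind the 3 patterns weighed first were all chosen after the results had been seen, while the 3 list contrasts after them come from lists fixed before the data were examined.

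Clusters 1, 2, 5, 11 and 12, which were frequent in marrow, held 1491 cells of the anti-Ly6G tumour library, 1243 of them in cluster 11, which its markers name as neutrophil, and clusters 2 and 11 were 5.78-fold more frequent there per monocyte/macrophage-like cell than under isotype (4.96 to 6.78). Carry-over from the marrow library, which came from a female by its Xist, would have brought 2103 Xist UMIs and 0 were seen, a number that allows up to 0.142% of the expected. Loss of the other neutrophil clusters alone is argued against by the 5.78-fold above. The neutrophils of the anti-Ly6G library held more Ly6g RNA than those of the isotype library (662 against 111 CPM). Cluster 11 made up 9.97% of the anti-Ly6G tumour library and 8.44% of marrow, so it was not particular to marrow. The immature cluster 2 held 54 cells of the anti-Ly6G tumour library and 2391 of marrow. A candidate explanation that stays open is the recruitment or survival, under anti-Ly6G, of neutrophils in clusters shared with marrow, mainly cluster 11. It was not tested, since each treatment is 1 library and the clusters were formed from genes that overlap with those compared.

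A C1q macrophage cluster (cluster 20) of the anti-Ly6G library carried neutrophil RNA, at least 28.1 times the level of S100a8, S100a9 and Retnlg in its other monocyte/macrophage-like cells, which argues against free RNA. For chance doublets, barcodes with C1q and neutrophil RNA were counted against the number expected if both occurred independently across barcodes, which is not a number of doublets. Observed over expected was 2.77 times higher (1.98 to 3.93) than in the isotype library (131 against 125 expected, and 49 against 129). The ratio for B cell RNA was 0.304 in the anti-Ly6G library. The anti-Ly6G neutrophils held more S100a9 RNA (113608 against 54011 CPM) and more UMIs per cell (median 4572 against 2340). Both make them easier to detect in a mixed barcode, and how sensitively B cell partners are seen was not measured. These counts therefore cannot decide on chance doublets. Uptake of antibody-coated neutrophils by macrophages, or attachment to them, may give this pattern, with an observed over expected ratio 3.46 times (2.58 to 4.66) that for B cell RNA in the anti-Ly6G library, but clumps formed during dissociation would give the same and cannot be told apart. The median doublet score of the cluster's cells was 0.209 against 0.0599 in the other monocyte/macrophage-like cells of that library.

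Genes induced by glucocorticoids were lower in the anti-Ly6G libraries in many cell classes: 6 noticed genes (Fkbp5, Tsc22d3, Klf9, Per1, Ddit4, Zfp36l2) had a median below 0 in 10 of 10 classes, from -1.52 to -0.36. For 15 further responsive genes, listed after this was noticed, the median was below 0 in 10 of 10 classes too, with an interval below 0 in 7, but 7 of those genes had been looked at, and the 8 others were below 0 in 9 classes, with an interval below 0 in 5, of which 3 lay at or below the 2.5th percentile of random lists. A different time of day stays open, since the clock arms were opposed in 1 of 3 classes with both measured, cholangiocyte-like cells (log2 -0.20 and 0.15). A weaker dissociation response is argued against outside neutrophils by the dissociation list, whose median over 9 classes was 0.082. In neutrophil-like cells that list was lower (-0.68), but the median over all measured genes there was -0.56. The list thus lay only slightly below other genes in neutrophils, and the explanation stays open there. Lower glucocorticoid exposure of the anti-Ly6G animals could lower these genes in many classes, but animals and antibody cannot be told apart in this design, and no replicate allows a test.

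The type I interferon response list went in opposite directions in hepatocyte/HCC-like cells (median log2 -0.61, -0.80 to -0.48) and monocyte/macrophage-like cells (0.19, 0.13 to 0.25), and the difference was not tested. So did the interferon-γ response list (-0.19, -0.25 to -0.13, and 0.27, 0.19 to 0.34), where the difference was not tested either. The T cell exhaustion list also did (-0.33, -0.56 to -0.11, and 0.19, 0.03 to 0.27), with 5 of 12 and 12 of 23 measured members prone to free RNA, and this difference was not tested. Of the CD45- barcodes, 73.6% (anti-Ly6G) and 75.7% (isotype) held less than 0.5% mitochondrial UMIs. In hepatocyte/HCC-like barcodes above that level Cxcl10, of the interferon-γ list, differed far less. Members of the type I list such as Ifit3b had low CPM in hepatocyte/HCC-like cells, and some were prone to free RNA.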

How the results depend on the processing

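Results by cluster or cluster mix, without single clusters, with marker genes left out of clustering, with the weak graph edges, at other subclustering resolutions, or with a mitochondrial minimum or doublet score limit in CD45- cells come from alternatives chosen after seeing the data; the others were fixed before. No paired analysis was possible because each group holds 1 library. A value is said to turn where its counting interval excludes 0 and its sign changed. Of 400 list medians recomputed, 2 turned under alternatives fixed in advance and 5 under those added. Of 1560 gene ratios, 12 and 20 turned, and of 154 share ratios, 3 turned, under alternatives fixed in advance. Counted together with values whose interval includes 0, 11 list medians, 42 gene ratios and 10 share ratios changed sign. Under those fixed in advance, 210 list medians, 695 gene ratios and 84 share ratios stayed within the counting interval of the reported value, and 83, 324 and 25 moved beyond it without turning. Under those added, 69, 299 and 37 stayed, and 31, 210 and 5 moved. Except where a clause says so, the cause was not tested. Thinning to 2000 UMIs left out 3188 of 8293 anti-Ly6G cells and 4336 of 10612 isotype hepatocyte/HCC-like cells. All values here are log2 ratios.

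The share of hepatocyte/HCC-like cells (-0.026, -0.068 to 0.015) was 0.029 at resolution 2.0, 0.032 with per-cell scores, 0.019 with the weak edges and 0.096 in barcodes with at least 0.5% mitochondrial UMIs. The neutrophil share of tumour to marrow was -0.30 at resolution 2.0, -0.36 with per-cell scores, -0.27 with the stricter mitochondrial limit, -0.34 with doublets kept and -0.29 clustered without the neutrophil markers, and that of anti-Ly6G to isotype was -0.77 with per-cell scores. Of cells other than neutrophils, by construction a smaller denominator, the shares of B cells (-0.027), T cells (-0.13) and NK/ILC1 cells (-0.035) turned, and that of monocyte/macrophage-like cells was 0.14, and with doublets kept 0.30.

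The tumour-associated neutrophil median of tumour to marrow was 2.63 with the mean of per-cell CPM, 2.87 with median-of-ratios scaling, 2.75 thinned to 1000 UMIs and 2.20 without the immature cluster. Tumour to spleen, H2-K1 turned to -0.26 with doublets kept. Anti-Ly6G to isotype, the tumour-associated neutrophil median was -0.89 with doublets kept, -0.67 with the mean of per-cell CPM, -0.46 with median-of-ratios scaling and -0.59 thinned. In the isotype cluster mix, it turned to 0.026, with Ltf at -0.095 and Siglecf at 0.19, but the clusters were formed from genes that overlap with the list. In cluster 11 alone it turned to 0.22, with Atf3 at 0.15, Gadd45b at 0.011 and Siglecf at 0.50. In cluster 13 alone it was -0.043, and the granule list (-0.33), Camp (-0.27), Itgb2l (-0.13), Ltf (-0.78), Ngp (-0.80) and Siglecf (0.21) turned. In cluster 14 alone it was -0.12, and the granule list (-0.048), Itgb2l (-0.15) and Stfa3 (-1.20) turned.

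The cytotoxicity median of T cells was 0.23 with median-of-ratios scaling, 0.25 with doublets kept and 0.39 without the γδ cluster, where Aqp3 (-0.071) and Cd163l1 (-1.05) turned. In NK/ILC1 cells thinned to 1000 UMIs, the cytotoxicity median (-0.024) and Ifng (-0.032) turned. In monocyte/macrophage-like cells without cluster 20, Lcn2 turned to -0.13, with the weak edges Lcn2 (-0.14) and Ltf (-0.019) turned, and with doublets kept Slfn4 (-0.022) turned.

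In hepatocyte/HCC-like cells the function list median was 0.039 with the mean of per-cell CPM, and there the proliferation list (-0.027), H2afz (-0.046) and Arg1 (0.0082) turned. With median-of-ratios scaling it was 0.071, and Arg1 (0.020) and H2-D1 (0.020) turned. Without cluster 10 it was -0.0025 and with at least 500 genes per cell -0.0024. Thinned to 2000 UMIs it was 0.032, and Arg1 (0.032), B2m (-0.021), Cyp2c54 (0.0084), H2afz (-0.022) and Tff3 (-0.081) turned. In barcodes with at least 0.5% mitochondrial UMIs it was -0.013, the MHC class I median was -0.16, and the proliferation list (-0.26), B2m (-0.092), H2afz (-0.11) and Tff3 (-0.22) turned.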

Other observations

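The cell classes described here were compared as in the report, and the lists named were chosen after their values were seen. Dendritic cells of the anti-Ly6G tumour had less RNA of Ddit4 and Fkbp5, and B cells of Zfp36l2. In conventional dendritic cells Ddit4, an mTOR inhibitor, had a log2 ratio to isotype of -1.88 (-2.09 to -1.68), Fkbp5 of -1.71, Klf9 of -1.70 and Tsc22d3 of -1.33. Of 16 MHC class II presentation genes, 2 were higher and none lower (median 0.41, 0.24 to 0.42), with the peptide-loading gene H2-DMb2 at 0.94 and H2-Eb1 at 0.50. The heat-shock genes Hspa1a (log2 1.23, 1.10 to 1.36) and Hspa1b (log2 1.23) were higher. In plasmacytoid dendritic cells (171 and 120 cells) the transcriptional inhibitor Id3 stood at 275 CPM under anti-Ly6G and 69.8 CPM under isotype (log2 1.98, 1.60 to 2.38), and the chemokine receptor Cxcr4 was lower (log2 -1.82). In B cells Zfp36l2, an mRNA-destabilising factor that holds back the cell cycle, stood at 219 and 921 CPM (log2 -2.07, -2.14 to -2.01), with Sesn1 (log2 -1.34), Pik3ip1 (log2 -1.07), Smad7 (log2 -1.05) and the phosphatase Ptpn22 (log2 -1.19) also lower. The B cell MHC class I median was 0.20 (0.15 to 0.21), and the granule protein median of 0.57 (0.37 to 1.52) shows neutrophil RNA in that class too.

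Cholangiocyte-like cells of the anti-Ly6G tumour had less of the keratin Krt7 (log2 -1.08), which also names the class, the small heat-shock protein Hspb1 (log2 -1.16, -1.24 to -1.09), the lectin Lgals3 (log2 -1.04) and Klf9 (log2 -1.11). Of 28 hypoxia and glycolysis genes in these cells, 3 were lower and none higher (median -0.28, -0.34 to -0.22), and Afp had a log2 ratio of 0.75. Hepatocyte function genes had a median of 0.26 (0.24 to 0.29) there. The class held much hepatocyte RNA, with Alb at 24822 and 20944 CPM and Afp at 1439 and 858 CPM. Cluster 3, with Agt, Igfbp1 and Cp beside Sox9 among its leading genes, held 25004520 of its 32129487 anti-Ly6G UMIs. Endothelial-like cells were few, 93 under anti-Ly6G and 150 under isotype, 0.893% and 1.15% of cells (fold 0.779, 0.595 to 1.02). In them the matrix gene Eln, which encodes elastin, had a log2 ratio of 4.43 (3.55 to 5.46), and Col6a3, a collagen VI chain, had 136 and 0 UMIs, at least 60.3-fold higher against a floor of 3 counts. The Wnt enhancer Rspo3 (log2 2.12) was higher, and the calcification inhibitor Mgp (log2 -5.48) and the neuropeptide Nts (log2 -3.89, -4.34 to -3.46) were lower. Hepatocyte transcripts such as Alb (log2 1.75) and Apoa1 (log2 2.15) were higher in them too. Hamp (log2 -3.57), Pck1 (log2 -2.54), Gstm3 (log2 -2.27) and Fmo5 (log2 -2.23), leading genes of hepatocyte/HCC-like clusters, were lower. RNA from other cells was thus present in this class and differed in both directions. Of 8 measured MHC class II genes, 5 were lower (median -3.10, -4.47 to -2.15), and of 26 hypoxia and glycolysis genes, 11 (median -0.44, -0.60 to -0.33). Whether the MHC class II RNA came from endothelial-like cells or from other cells was not tested.

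Neutrophil RNA was also seen in a CD45- cluster. Cluster 15 of the CD45- libraries, which had macrophage and neutrophil markers and was left unnamed, held 111 cells under anti-Ly6G and 101 under isotype. It carried 161 and 2 UMIs of Ly6g, and S100a8 stood at 34634 and 2816 CPM. The sort excluded CD45+ cells, so these barcodes passed the gate with immune RNA.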
